A study of Leucocroton havanensis with 4 samples.

How the data were processed

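The data comprised 4 RNA-seq libraries of Leucocroton havanensis, 1 each for root without nickel, root with nickel, shoot without nickel and shoot with nickel. Per the labels' protocols, tissue was stabilised in RNAlater, total RNA was extracted with TRIzol LS and treated with DNase, and stranded polyA libraries were made with an Illumina TruSeq kit and read as paired ends. Per the file headers, each deposited file gives the read count of 1 library per contig, and the values are whole-number counts without normalization. The aligner, the counting program, the assembly behind the contigs and any filter are not given in the sources used here. The contigs have no genome coordinates in these files, and gene names, lengths and sequences were not used here.

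All 4 files listed the same 65936 contigs, of which 1 had no read in any library. The total counts were 59802565 for root without nickel, 55660570 for root with nickel, 84917997 for shoot without nickel and 98108920 for shoot with nickel. Even numbers made up 55.5% to 61.6% of the counts from 1 to 20, and a count of 2 was more frequent than a count of 1 in every library (3066 against 1649 in root without nickel). Such an excess would arise if both reads of some pairs were counted, and counting intervals and floors are too narrow to the extent that this holds. They include no biological or technical variation. How reads were divided among near-identical contigs, such as alleles or gene copies, is not given in the sources used here. A zero count was set at a floor of 3 reads per library, which was 0.050 CPM in root without nickel, 0.049 CPM in root with nickel, 0.041 CPM in shoot without nickel and 0.029 CPM in shoot with nickel.

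Contigs with at least 10 reads in at least 1 library were kept, which left 60628 (91.9%). Library sizes were scaled by TMM over the 4 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The TMM factors were 1.00, 1.11, 0.867 and 1.04 in the order of libraries above. Log2 ratios were taken between CPM values with a prior count of 2. The ratio of 2 counts was given an exact 95% interval (conditional binomial, Clopper-Pearson). A contig was taken as differing when its log2 ratio was at least 2 in size, that is 4-fold, and its interval excluded folds below 1.5 in that direction. This is a rule of size and not a test, since each group had 1 library. The only count model with a residual degree of freedom was an additive one with organ and nickel as terms, fitted with edgeR's quasi-likelihood method and Benjamini-Hochberg adjustment. Its calls measure spread by 1 residual degree of freedom, moderated by a value shared over all contigs, among 4 libraries that are not replicates. DESeq2 1.42.0 was run with the same design as an alternative. Overlaps of contig lists are set against the number that independent lists of the same lengths would share.

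Groups, tests, the size rule and the rule for named contigs were fixed before the data were examined. For files with identifiers only, that rule named, in each nickel comparison and in the organ comparison without nickel, the contig higher and the contig lower whose interval lay farthest from 1, among those with at least 100 reads in the 2 libraries. The 27 gene lists prepared in advance, on metal transport, metal ligands, iron deficiency, photosynthesis and other functions, needed gene names, so none of them could be formed. Alternatives were DESeq2 size factors, total counts, other filters, prior counts of 0.5 and 5, an 8-fold threshold and thinning of each library to the smallest total. Intervals from halved counts, scaling on abundant contigs, a restriction to contigs of mean CPM 10 or more under several scalings and the omission of the shoot library with nickel were added after the data were seen.

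The calculations were tested on simulated data with the real contig means and library sizes and 200 changed contigs. The changed contigs were drawn only from those above a minimum expected read count in the smallest library. The shares recovered and held below therefore do not cover the least abundant contigs, where many real contigs past the size rule lie. With counting error only, the root comparison recovered 96% of 6-fold and 100% of 16-fold changes, the intervals held the true fold for 96% of the changed contigs, and 35 unchanged contigs passed. At an assumed coefficient of variation of 0.4 between libraries, the same comparison recovered 77% and 99%, the intervals held the true fold for 36%, and 1462 unchanged contigs passed, of which 296 were of mean CPM 10 or more. In the shoot comparison the unchanged contigs passing numbered 16 with counting error only, 56 at 0.2 and 1352 at 0.4, of which 261 were of mean CPM 10 or more.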

Results

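Leucocroton havanensis is a Cuban shrub of the Euphorbiaceae that accumulates nickel in its tissues to very high concentrations. RNA sequencing was used to compare the transcripts of its roots and shoots after growth with and without nickel. Plantlets were raised in vitro on agar medium for 6 weeks after germination, and the growth protocol gives 500 mg/L NiSO4 in the medium. That protocol is worded alike for all samples, so the dose is taken to apply to the samples labelled with nickel. The 4 groups were root without nickel, root with nickel, shoot without nickel and shoot with nickel, each with 1 library. No difference between groups therefore had a replicate check, and the intervals given cover counting error only. The shoot library with nickel was labelled as a re-analysis of a library from an earlier series, whereas the other libraries carried no such label. Reads were counted on 65936 contigs, that is, sequences of a transcript set with its own numbering. The files used here do not pair the contig identifiers with gene names, so no transcript could be assigned a function.

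The libraries held 59802565 counted reads for root without nickel, 55660570 for root with nickel, 84917997 for shoot without nickel and 98108920 for shoot with nickel. At least 10 reads were counted on 45276 contigs in root without nickel and on 47771 in root with nickel. The same level was reached by 46286 contigs in shoot without nickel and by 53825 in shoot with nickel. The 100 most abundant contigs took 19.3% and 19.99% of the reads in root without and with nickel, and 29.2% and 26.8% in shoot without and with nickel. The Spearman correlation across 60628 contigs was 0.96 between the root libraries and 0.93 between the shoot libraries. Between organs it was 0.81 without nickel and 0.76 with nickel.

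Root and shoot differed far more than nickel-grown and nickel-free plantlets did. Without nickel, 7460 contigs were at least 4-fold higher in root and 6142 were at least 4-fold higher in shoot, together 22.4% of the 60628 contigs tested. With nickel, 7568 contigs were higher in root and 7562 in shoot. That balance depended on the scaling, with 8003 and 7053 by total counts and 6975 and 8597 with scaling on abundant contigs. Contigs higher in root without nickel were also higher in root with nickel in 4466 cases, against 931 for independent lists. Those higher in shoot were shared in 3899 cases, against 766 for independent lists. The contigs that differed took 36.7% of the shoot reads and 18.2% of the root reads without nickel. The organ ratios measured without and with nickel shared no library, and they correlated across contigs with Pearson's r = 0.76 and Spearman's rho = 0.71, although contigs are not independent replicates. In reversed directions, 71 contigs were higher in root without nickel and higher in shoot with nickel, and 66 showed the opposite. The organ comparison with nickel used the re-analysed shoot library, so organ and library origin coincide in it. Among the 13685 contigs with a mean of at least 10 CPM (read count relative to the TMM-scaled library size) over the 4 libraries, 1047 were higher in root and 1273 in shoot without nickel.

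The contig that stood furthest above shoot in root without nickel was Lhav_v2_contig_63928. It had 11982 reads (200 CPM) in root without nickel and none in shoot, which is at least 4904-fold higher in root when the shoot is set at a floor of 3 reads per library. With nickel it had 8140 reads (132 CPM) in root and again none in shoot. The contig furthest in the other direction was Lhav_v2_contig_662, with 250802 reads (3409 CPM) in shoot without nickel and none in root, at least 68094-fold lower in root. In the libraries with nickel it had 227608 reads (2238 CPM) in shoot and none in root. The floor at which a zero count was set was 0.050 CPM in root without nickel and 0.041 CPM in shoot without nickel.

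In an additive model over the 4 libraries with organ and nickel as terms, 12153 contigs differed between organs (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 6649 were higher in root and 5504 were higher in shoot. The model had 1 residual degree of freedom, which was the dependence of the nickel difference on organ. For each contig, the measure of spread joined it to a value shared over all contigs, weighted as 3.66 degrees of freedom.

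**Figure D1:**
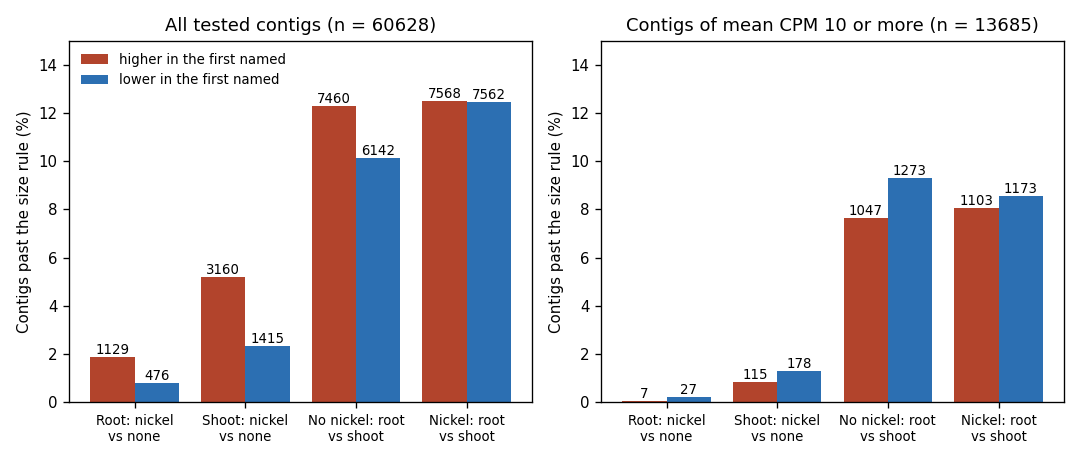
Percentage of contigs (y axis) at least 4-fold higher (red) or lower (blue) in the first named library of each comparison (x axis), with the number of contigs above each bar, for all 60628 tested contigs (left) and for 13685 contigs of mean CPM 10 or more (right). The organ comparisons give the tallest bars, and among abundant contigs the root nickel comparison has 7 higher and 27 lower.

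Nickel was associated with few large differences in root. Between root with and without nickel, 1129 contigs were at least 4-fold higher with nickel and 476 were at least 4-fold lower, 2.65% of those tested. Together they took 0.131% of the reads of root with nickel. Of all tested contigs, 81.5% lay within 2-fold, and the median absolute log2 ratio was 0.38. Among contigs of mean CPM 10 or more, 7 were higher and 27 lower, and the median absolute log2 ratio was 0.21. The largest increase relative to counting error was that of Lhav_v2_contig_20894, with no reads in root without nickel and 397 reads (6.43 CPM) in root with nickel. Against the floor of 3 reads per library it was 128-fold higher (95% exact lower limit 104). In shoot the same contig had 26 reads (0.353 CPM) without nickel and none with nickel. The largest decrease was that of Lhav_v2_contig_2671, from 1530 reads (25.5 CPM) to 9 reads (0.146 CPM), 175-fold lower with nickel (95% exact interval 92.1 to 384). In shoot it stood at 19.9 CPM without and 77.0 CPM with nickel, a log2 ratio of 1.95 (95% exact interval 1.87 to 2.04).

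Most root contigs past the 4-fold size were of low abundance, with 502 higher and 51 lower in the lowest of 10 equal classes of mean abundance and 1 higher and 3 lower in the highest. Low counts were more often even than odd numbers, and with counting intervals from halved counts the total of 1605 became 705. In simulated libraries with 200 changed contigs, 121 unchanged contigs of the root comparison passed at an assumed biological coefficient of variation of 0.2 and 1462 passed at 0.4. Of the unchanged contigs of mean CPM 10 or more, 0 passed at 0.2 and 296 at 0.4, whereas 34 were past the size rule in the real root libraries. A value of 0.4 was therefore too large for the abundant contigs of this comparison.

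In shoot, more contigs were past the 4-fold size than in root. With nickel, 3160 contigs were higher and 1415 lower, 7.55% of those tested, and they took 1.68% of the reads of shoot with nickel. Of all tested contigs, 73.7% lay within 2-fold, and the median absolute log2 ratio was 0.51. Among contigs of mean CPM 10 or more, 115 were higher, 178 were lower, and the median absolute log2 ratio was 0.29. The balance depended on the scaling, with 157 higher and 135 lower by total counts and 99 higher and 196 lower by DESeq2 size factors. Over all tested contigs, 3932 were higher and 1111 lower by total counts, and 2648 and 1533 by DESeq2 size factors. Differences of at least 32-fold were found for 127 contigs higher and 235 contigs lower with nickel, compared with 38 and 11 in root. Lhav_v2_contig_4036 had no reads in shoot without nickel and 5249 reads (51.6 CPM) with nickel, at least 1266-fold higher. In root it had 58 reads (0.968 CPM) without nickel and none with nickel. Lhav_v2_contig_5910 had 5853 reads (79.6 CPM) in shoot without nickel and none with nickel. Against the same floor it was 2697-fold lower (95% exact lower limit 2193). In root it was present in both libraries, at 36.1 CPM without and 24.8 CPM with nickel, a log2 ratio of -0.54 (95% exact interval -0.63 to -0.44).

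Because the shoot library with nickel came from an earlier series, nickel and library origin cannot be told apart in the shoot comparison. Of 23365 contigs with at least 1 CPM in each of the other 3 libraries, 153 stood at least 32-fold below the lowest of these in shoot with nickel, Lhav_v2_contig_5910 among them. This limit was chosen after the data were seen. The corresponding numbers were 36 for shoot without nickel, 8 for root with nickel and 3 for root without nickel. With intervals from halved counts, the total of 4575 shoot contigs became 2906. Among contigs of mean CPM 10 or more, 293 were past the size rule in shoot. In the simulated shoot comparison, 0 unchanged contigs of that abundance passed at an assumed coefficient of variation of 0.2 and 261 at 0.4. That count alone therefore does not set the 293 apart from unchanged contigs at 0.4.

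**Figure D2:**
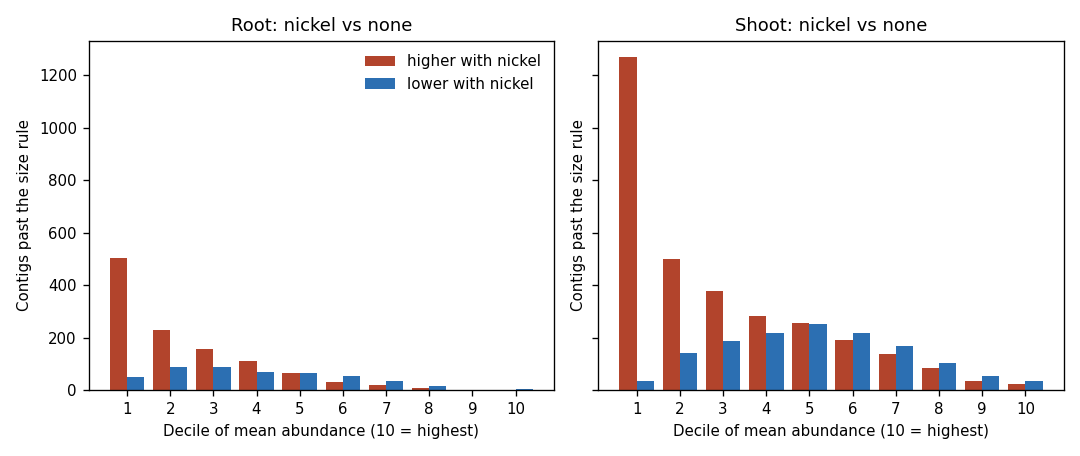
Number of contigs (y axis) at least 4-fold higher (red) or lower (blue) with nickel in root (left) and shoot (right), in 10 equal classes of mean abundance over the 4 libraries (x axis, 10 the most abundant). In the lowest class 1268 contigs were higher and 36 lower in shoot, and in the highest class 23 were higher and 36 lower (30 and 25 by total counts).

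More contigs were higher than lower with nickel in the 4 lowest abundance classes in root and the 5 lowest in shoot. In the remaining classes the lower contigs were as many as the higher ones or more. That held for TMM, whereas by total counts more contigs were higher than lower in all 10 classes in shoot, with 30 higher and 25 lower in the highest class. In root, total counts turned class 5 to 90 higher and 55 lower (65 and 67 by TMM). Class 7 turned to 29 higher and 25 lower (21 and 34 by TMM). A total of 755 contigs had at least 10 reads in the libraries with nickel combined and none in the libraries without nickel, whereas 0 contigs showed the reverse. For comparison, 1205 contigs were counted in root libraries alone and 1543 in shoot libraries alone by the same rule.

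In these libraries, the nickel differences of root and shoot had little in common. The shoot ratios include any difference of library origin, so unlike ratios need not mean unlike responses to nickel. Across the 60628 contigs, the log2 ratios in root and shoot correlated with Pearson's r = -0.0088 and Spearman's rho = 0.025. Among contigs of mean CPM 10 or more, where ratios spread less, these values were -0.077 and -0.0021. The comparisons shared no library. In all, 58 contigs were higher with nickel in both organs, against 58.8 for independent lists and 143 for independent lists within the 10 abundance classes. Another 18 were lower in both, against 11.1 for independent lists and 13.6 within the abundance classes. In opposite directions, 62 contigs were lower in root and higher in shoot, against 24.8 and 32.4 by the same measures. A further 46 were higher in root and lower in shoot, against 26.3 and 21.7. The abundance classes rest on the mean of the same 4 libraries, so the numbers within them depend on the ratios compared. No result is drawn from the shortfall of 58 against 143. Among contigs of mean CPM 10 or more, 0 were higher in both organs, against 0.059 for independent lists and 0.18 within the abundance classes, and 2 were lower in both, against 0.35 and 2.36. Of the 27 such contigs lower in root, 6 were higher in shoot, against 0.23 for independent lists and 1.36 within the abundance classes. Another 1 was higher in root and lower in shoot, against 0.091 and 0.43.

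The log2 ratio in root differed from that in shoot by at least 2 for 4502 contigs that were past the 4-fold size in at least 1 organ. It was above the shoot ratio for 1909 of them and below it for 2593. This balance turned with a prior count of 5 (1166 above, 1131 below), an 8-fold threshold (766 and 618) and contigs of mean CPM 10 or more (156 and 109). These differences between organs were not tested, since each group had 1 library. In the additive model, 0 contigs had a nickel difference common to both organs at an adjusted p under 0.05 (edgeR quasi-likelihood test), with a smallest adjusted p of 0.97. An unadjusted p under 0.05 was reached by 1807 contigs, compared with 3031 for chance, and DESeq2 with the same design called 48 contigs, 17 higher and 31 lower. The fit put the coefficient of variation between libraries at 0.41. Without replicates, this value includes the dependence of the nickel difference on organ and any difference of library origin. In simulated libraries, 200 contigs above a minimum expected read count were raised 16-fold by nickel in both organs. At an assumed coefficient of variation of 0.4, the same edgeR fit called 191 of them and 0 others. At 0.2 it called all 200 and 6 others. Every simulated contig had the same coefficient of variation and no dependence of the nickel difference on organ. The simulation therefore does not give the share of common nickel differences that the fit would find in the real libraries.

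**Figure D3:**
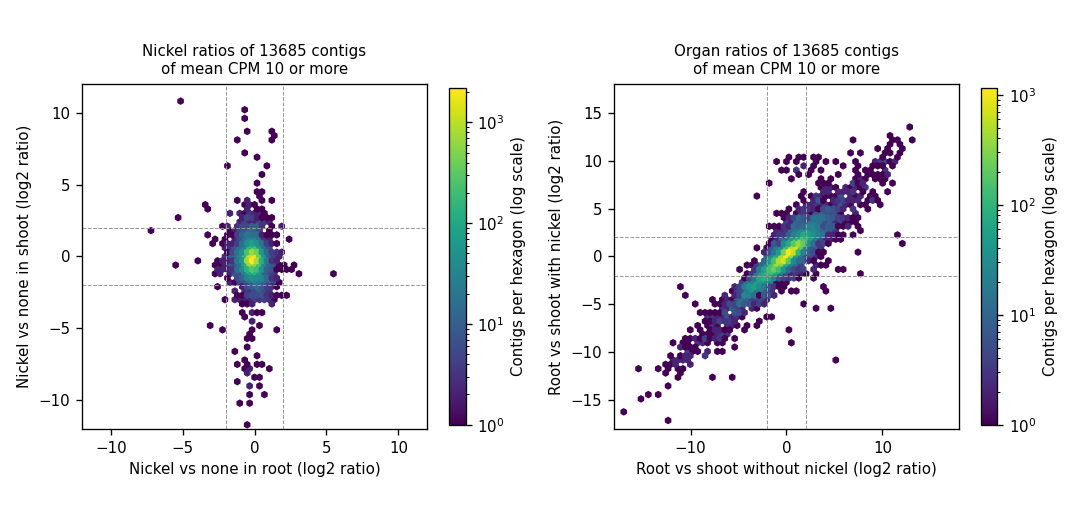
Log2 ratios of 13685 contigs of mean CPM 10 or more, as contigs per hexagon on a log colour scale: left, nickel against no nickel in root (x axis) and shoot (y axis), and right, root against shoot without nickel (x axis) and with nickel (y axis), with dashed lines at a log2 ratio of 2 in each direction. Nickel ratios spread more in shoot than in root, and organ ratios lie along the diagonal.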

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

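The items here were listed because the nickel difference had opposite directions in root and shoot. With 1 library per group, the difference between the organs was not tested. In all, 108 contigs were past the 4-fold size in both organs in opposite directions. Lhav_v2_contig_20894 was higher with nickel in root and lower in shoot, and its log2 ratio in root exceeded that in shoot by 11.72. Lhav_v2_contig_4036 was lower with nickel in root and higher in shoot, and its log2 ratio in root minus that in shoot was -16.11. Both contigs had no reads in 2 of the 4 libraries, so these log2 values depend on the prior count.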

How the results depend on the processing

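Of 77 recalculations of the 8 counts and correlations, 50 stayed within 1.5 times the reported count, or within 0.05 of the reported correlation. The rest are given here for nickel in root, nickel in shoot, root against shoot without nickel, root against shoot with nickel, and the difference of the nickel ratios between organs (reported as 1605, 4575, 13602, 15130 and 4502 contigs). With at least 50 reads required, fewer contigs entered, and the counts were 568 in root, 2220 in shoot, 9421 for the organs with nickel and 2151 for the difference between organs. A prior count of 5 gave 659, 2271 and 2297 for root, shoot and their difference. An 8-fold threshold gave 404, 1284, 6756, 7605 and 1384 in the order above. Added after the data were seen, intervals from halved counts gave 705 in root, 2906 in shoot and 2887 for their difference. A restriction to 13685 contigs of mean CPM 10 or more gave 34, 293, 2320, 2276 and 265, a correlation of the nickel ratios of -0.077, and 6136 organ calls in the additive model. The share of higher among the shoot nickel contigs went from 69.1% to 53.0% with the 8-fold threshold and to 56.1% with a prior count of 5 or at least 50 reads. In root it was 77.0% with the 8-fold threshold, 67.2% with a prior count of 5 and 58.1% with at least 50 reads. Shares turned under the restriction to abundant contigs, from 70.3% to 20.6% in root and to 39.2% in shoot. With total counts under that restriction, 24.2% of 33 contigs were higher in root and 53.8% of 292 in shoot, and with DESeq2 size factors 20.6% of 34 and 33.6% of 295. DESeq2 called 48 contigs for nickel in the additive model where edgeR called 0, with 28211 adjusted p-values undefined, and the cause was not tested. Total counts in place of TMM moved the median log2 ratio from 0.050 to 0.29 in shoot, from -0.033 to 0.079 in root and from 0.053 to 0.25 for the organs without nickel. Scaling on abundant contigs moved it from -0.086 to -0.24 for the organs with nickel. Without the shoot library with nickel, 1505 contigs differed in root and 13248 between organs without nickel. The 6 named contigs kept their direction in all 18 recalculations. Gene lists were not run, for want of names. Leaving out a replicate was not run, since it would remove a group. No paired analysis was possible because the groups share 1 replicate number, and the additive model took organ as its block. Depth limited contigs of low abundance, where 3 reads corresponded to 0.029 to 0.050 CPM.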

Other observations

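Thinning to equal depth and the 8-fold threshold were planned for all contigs. The other tests here, with those on abundant contigs among them, were chosen after the results were seen. Contigs numbered above 60000 reached 10 reads more often in root than in shoot libraries. Of these 5936 contigs, 54.2% had at least 10 reads in root with nickel, 39.1% in root without nickel, 15.1% in shoot without nickel and 12.8% in shoot with nickel. Among contigs 1 to 60000 the shares were 74.3%, 71.6%, 75.7% and 88.4%. Contigs at least 100-fold higher in shoot than in root without nickel, at 50 CPM or more in shoot, numbered 76. Their median level in root was 0.077% of that in shoot without nickel and 0.098% with nickel.

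More contigs were higher than lower with nickel, 69.4% of the nickel contigs over both organs. At the 8-fold threshold the share of higher contigs was 77.0% in root and 53.0% in shoot. Sequencing depth is argued against as the whole cause, because 65.8% were still higher after thinning to equal depth. A contig set built from the libraries with nickel is a candidate explanation: at equal depth 488 contigs had at least 10 reads with nickel and none without, and 0 showed the reverse, while 1457 were found in root alone and 1125 in shoot alone. That more genes rise than fall with nickel stays open for contigs of mean CPM 10 or more over both organs. There 37.3% were higher with TMM, 32.2% with DESeq2 size factors and 50.8% with total counts. This pooled balance rests mostly on shoot contigs and depends on the scaling. In root it did not turn, with 7 higher and 27 lower by TMM and by DESeq2 size factors. By total counts, 8 were higher and 25 lower in root. More of the abundant contigs past the size rule therefore fell than rose in these root libraries. For less abundant contigs, of which 71.2% were higher, a rise of more genes than fall stays open as well. A contig set built from the libraries with nickel would give the same sign.

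The shoot library with nickel lacked or almost lacked 153 contigs that the other 3 libraries held. It had no reads for 104 of them, and shoot without nickel had none for 16 of its corresponding 36. The smallest number of reads expected for any of the 153 was 103.7, which follows from the limit of 1 CPM by which they were chosen. Sampling at low depth therefore cannot account for contigs chosen in this way. A lowering by nickel in both organs is argued against by 161 such contigs chosen without use of root with nickel. Of these, 3 were at least 4-fold lower in root, and the median log2 ratio in root was -0.16 (median absolute deviation 0.57). Their median of -6.68 in shoot was low by the way they were chosen. Plants of another origin in the re-analysed library, carrying other alleles or lacking some sequences, may account for them, and so may an effect of nickel in shoot alone. These cannot be told apart, because 0 shoot libraries with nickel were free of the re-analysis label.

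Nickel differences were more numerous in shoot than in root, and log2 ratios spread wider, although contigs higher with nickel had a median log2 ratio of 2.61 in root and 2.48 in shoot, and those lower -2.57 and -2.75. Depth of the shoot libraries is argued against, because at equal depth 3585 contigs differed in shoot and 1421 in root (4575 and 1605 before), and 293 and 33 among abundant contigs, a ratio of 8.88 (8.62 before). Root tissue in the shoot library with nickel is argued against for the 63 abundant contigs that were higher in root than shoot without nickel and higher in shoot with nickel. They stood at a median of 43.0% of their root level (quartiles 12.9% and 198%), whereas 64 root-specific contigs stood at 0.354% (quartiles 0.012% and 1.66%), 5 of them at 12.9% or more. Library origin or another batch may account for the spread of the log2 ratios, which was 1.44 times as wide in shoot as in root among abundant contigs, and it cannot be told apart from a stronger response of the shoot to nickel, since nickel and library origin coincide there.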
